A study of Sus scrofa with 2 samples.

How the data were processed

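DNA from muscle biopsies of Hampshire and Mali pigs was profiled by methylated DNA immunoprecipitation sequencing (MeDIP-seq), in which fragments that carry methylated cytosine are precipitated and sequenced. There was 1 library per breed. Per the labels' protocols, the precipitated fragments were amplified by adaptor-mediated PCR, 8.5 pmol of library was loaded, and paired-end reads of 100 bp were collected on an Illumina HiSeq 2500. Per the submitters' processing notes, FastQC 0.11.9, cutadapt 3.3 and BWA were used on the reads. The genome named in the deposited table is the UCSC build susScr11 of the pig. How duplicates were treated, whether reads were extended to fragments, which mapping qualities were kept and which program made the table are not given in the sources used here. Duplicate removal could bear on the mitochondrial values, since that genome is small and covered many times, but its effect was not measured.

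The deposited table holds 42 rows, 21 per library: 18 autosomes, chromosomes X and Y, and the mitochondrial genome. Per the file's column legend, the authors deposited raw counts of CpG dinucleotides, of C and of G in the sequenced regions of each chromosome, and the counts of the same items in the reference genome. They also deposited the CpG density, as the percent of sequenced positions at which a CpG lies (CpGs per 100 bases), and the ratio of observed to expected CpG. An enrichment score, also deposited by the authors, is the ratio of each of these values to that of the whole genome. The score of a chromosome is thus set against the whole genome and not against that chromosome, so it holds the chromosome's own CpG content as well as any enrichment. Recomputed scores differed from the deposited ones by a relative difference of at most 6.4e-15. The table holds no value for a gene, a peak or a CpG site.

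The number of sequenced bases behind each row was recovered from the CpG count and the CpG density, and a second time from the CpG count, the C and G counts and the observed-to-expected ratio. All 42 rows gave whole numbers within 0.001 bases. On simulated data 42 of 42 known lengths were returned, which checks the code only, because the recovery inverts the formula that made those data. GC content and the ratio of C to G were then computed per row. Values over several chromosomes were pooled by summing counts and bases. Depth per chromosome was the number of sequenced bases divided by the end of the last annotated gene in the RefSeq gene table of Sscrofa11.1, a stand-in for chromosome length. The reference length recovered from the deposited genome values was 2435 Mb, against 2432 Mb for the summed gene ends of the same 21 sequences. Numbers of reads cannot be recovered from the table.

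With 1 library per breed there is no spread between animals, so no test between breeds was made and no p-value is given. Differences are differences between these 2 libraries. Intervals are 95% Wilson intervals for densities and shares, and log-scale intervals for ratios of densities. They cover counting error only and are too narrow, because neighbouring bases of one read, overlapping reads and PCR copies are not independent. Correlations are across the 18 autosomes, which are not independent replicates. Each was recomputed without the 2 autosomes farthest from the median of the first measure.

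Before the data were examined, the rule for chromosomes named in the text was fixed: the 3 highest and 3 lowest for each measure in each library, the 3 largest differences each way, the sex chromosomes and the mitochondrial genome. CpG density, observed-to-expected CpG, GC content and sequenced bases were taken as the measures. The gene lists fixed at the same time had no values in the table and were used only to say which chromosome a gene lies on. The alternatives tried were scaling each library by its total or its median, other summaries over chromosomes, autosomes alone, a filter on the smallest chromosomes, a 1.5-fold minimum and pseudocounts. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.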

Results

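Precipitated DNA from muscle of Hampshire and Mali pigs was compared by its CpG content, which describes base composition and does not measure methylation. The Hampshire library held 4.17 Gb of sequenced bases with 36003938 CpGs, and the Mali library held 2.40 Gb with 21344170 CpGs. These totals equal 1.71 and 0.987 times the length of the reference genome. Overlapping regions were counted each time they were sequenced. Each autosome carried between 1.35 and 1.95 bases per base of annotated length in the Hampshire library and between 0.804 and 1.11 in the Mali library. Each breed was represented by 1 library, so every difference below is one between 2 libraries and has no replicate check.

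The first comparison asked how the CpG content of the precipitated DNA stood against the genome. In both libraries the nuclear DNA was poorer in CpG than the genome as a whole. The reference genome held 1.22 CpGs per 100 bases. The nuclear reads of the Hampshire library held 0.859 (95% Wilson interval 0.8586 to 0.8591), which is 0.705 times the genome, and those of the Mali library held 0.878 (0.8778 to 0.8786), which is 0.721 times the genome. A library that sampled the genome evenly would stand at 1, and a library enriched in CpG would stand above 1. The ratio of observed to expected CpG, which takes the numbers of C and G into account, was 0.228 in Hampshire and 0.233 in Mali, against 0.285 in the genome. GC content was 38.8% and 38.9% in the nuclear reads of Hampshire and Mali, and 41.3% in the genome. The median score over the 21 sequences was 0.750 in both libraries for CpG density and 0.847 in both for observed-to-expected CpG.

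Chromosome 12 was the nuclear chromosome with the most CpG-rich reads in each library. Its reads held 1.48 CpGs per 100 bases in Hampshire and 1.56 in Mali, and their GC content was 43.2% and 43.7%. It was the only nuclear chromosome with a density score above 1, at 1.22 in Hampshire and 1.28 in Mali. Chromosome 12 also has the highest density of annotated protein-coding genes among the nuclear chromosomes, 18.2 per Mb, and carries the cluster of MYH4, MYH1 and MYH2, which encode fast myosin heavy chains of skeletal muscle (Sscrofa11.1, positions 55190545 to 55278820). Chromosome 10 followed, with 1.12 CpGs per 100 bases in Hampshire and 1.14 in Mali. Each score is set against the whole genome, so it holds the chromosome's own base content. None of these values is specific to a gene.

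The lowest CpG densities lay on chromosomes 13, 1 and 15, in that order in both libraries. Chromosome 13 stood at 0.662 CpGs per 100 bases in Hampshire and 0.645 in Mali. Chromosome 1, the largest chromosome, stood at 0.683 and 0.690. Chromosome 15 stood at 0.683 and 0.699. Chromosome 15 carries MSTN, which encodes myostatin, a secreted inhibitor of muscle growth (positions 94623526 to 94628440), together with TTN (84226953 to 84501320) and NEB (546187 to 766131), which encode the giant sarcomere proteins titin and nebulin. The table gives 1 value per chromosome, so none of these values is that of a gene. The observed-to-expected ratio gave the same 3 chromosomes as lowest, from 0.187 on chromosome 13 to 0.195 on chromosome 15 in Hampshire and from 0.183 to 0.200 in Mali. GC content was lowest on chromosomes 8, 15 and 11, at 37.1%, 37.4% and 37.6% in Hampshire and 37.1%, 37.4% and 37.5% in Mali. After chromosome 12, it was highest on chromosome Y, at 42.5% and 42.7%, and chromosome 17, at 41.3% and 41.5%.

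**Figure D1:**
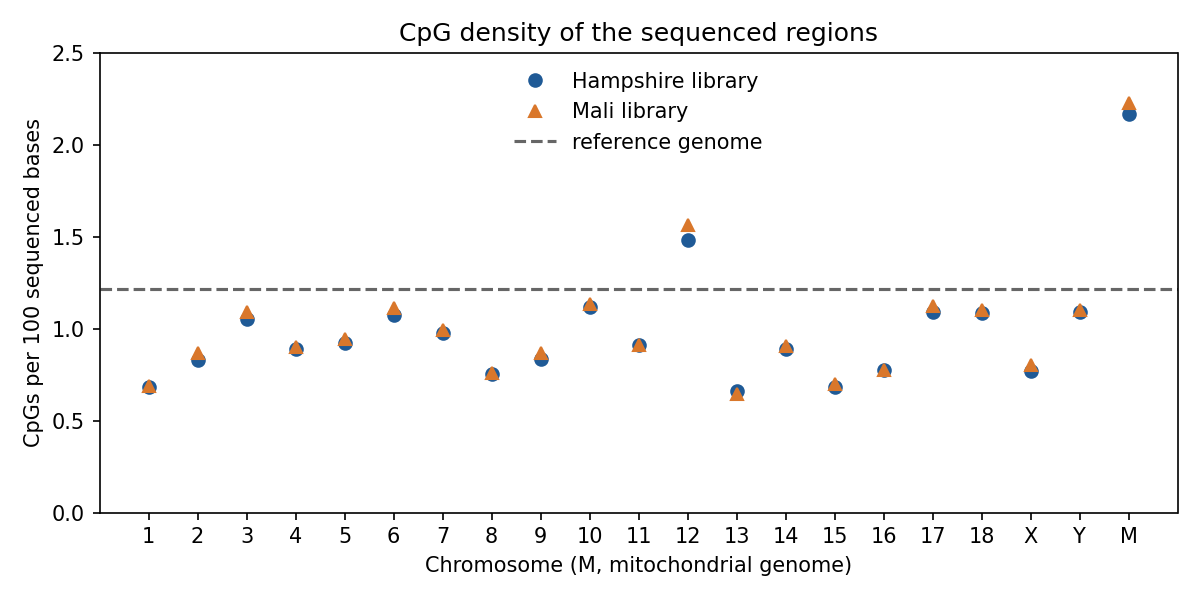
CpGs per 100 sequenced bases (vertical axis) on each chromosome (horizontal axis) in the Hampshire library (circles) and the Mali library (triangles), with the reference genome as a dashed line at 1.22. Chromosome 12 and the mitochondrial genome are the only sequences above the line in either library, and the libraries lie close together on each chromosome.

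The ranking of the autosomes by CpG density was nearly the same in both libraries (across 18 autosomes, Pearson's r = 0.998 and Spearman's rho = 0.998; r = 0.997 without chromosomes 12 and 13). Density was higher on autosomes with more protein-coding genes per Mb, with r = 0.69 and rho = 0.47 in Hampshire and r = 0.73 and rho = 0.48 in Mali. Without chromosomes 2 and 12, r was 0.56 and 0.60. Both libraries were placed on the same reference, so each chromosome's own CpG content enters these relations and was not removed. Depth was lower on GC-rich autosomes. Chromosome 12 had the lowest depth in both libraries, 1.35 in Hampshire and 0.804 in Mali. Chromosomes 13 and 1 had the highest, 1.95 on chromosome 13 in Hampshire and 1.11 on chromosome 1 in Mali. Across autosomes, GC content and depth gave r = -0.977 and rho = -0.950 in Hampshire and r = -0.972 and rho = -0.942 in Mali. Without chromosomes 12 and 17, r was -0.961 and -0.949. With gene density in place of GC content, r was -0.790 in Hampshire and -0.758 in Mali, with rho -0.651 and -0.635. Without chromosomes 2 and 12, r was -0.724 and -0.697. In all, 9 such relations across the autosomes were computed.

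**Figure D2:**
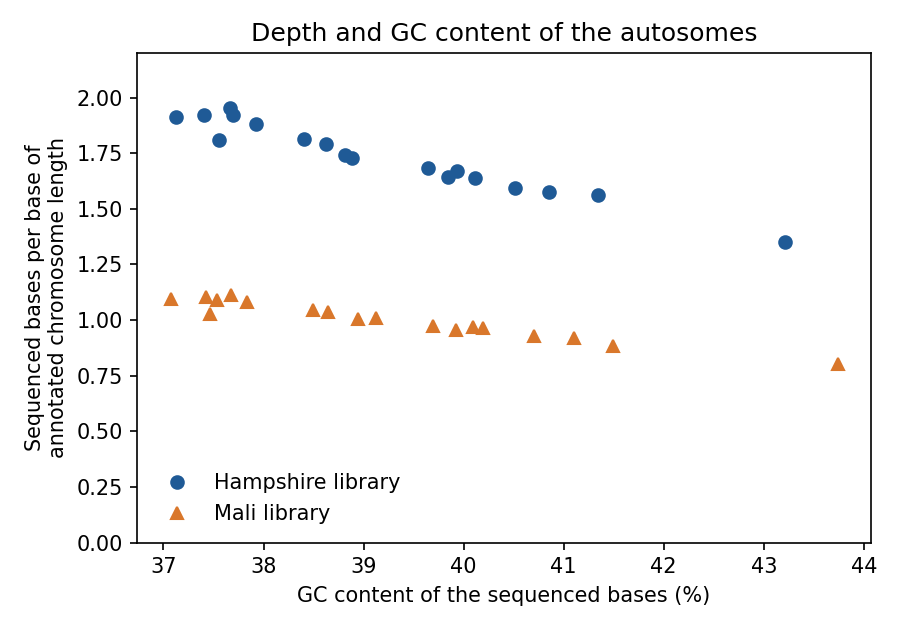
Sequenced bases per base of annotated chromosome length (vertical axis) against the GC content of the sequenced bases in percent (horizontal axis), with 1 point per autosome and library. Depth falls as GC content rises in both libraries, with chromosome 12 at the lower right of each series at 1.35 (Hampshire, circles) and 0.804 (Mali, triangles).

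The second comparison was between the breeds. Reads of the Mali library were slightly richer in CpG than those of the Hampshire library. The pooled nuclear density was 2.25% higher in Mali, and the density was higher in Mali on 19 of 21 sequences, the exceptions being chromosomes 13 and 16. Over the 18 autosomes the median Mali-over-Hampshire ratio was 1.020, with an SD between autosomes of 0.0190. The rise was largest on chromosome 12, where the Mali library was 5.68% higher (ratio 1.057, interval 1.054 to 1.060), followed by chromosome X at 4.49% (1.045, 1.041 to 1.048) and chromosome 2 at 4.43% (1.044, 1.042 to 1.047). Chromosome 2 carries MYOD1 (41422522 to 41424236), a master regulator of the muscle lineage, and IGF2 (1469183 to 1496417), an imprinted growth factor gene. Its value is that of the whole chromosome, with 2683 annotated genes, and not that of either gene. In absolute density the largest gaps, Mali above Hampshire, were 0.0841 CpGs per 100 bases on chromosome 12, 0.0637 on the mitochondrial genome and 0.0409 on chromosome 6.

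Chromosome 13 went the other way. Its CpG density was 0.645 in Mali and 0.662 in Hampshire, a ratio of 0.974 (interval 0.972 to 0.976). On chromosomes 16 and 11 the interval of the ratio included 1, at 0.997 to 1.003 and 0.998 to 1.003. On chromosome Y the ratio was 1.008 (1.002 to 1.015). The observed-to-expected ratio was also higher in Mali on 19 of 21 sequences, with chromosomes 13 and Y as the exceptions. Its Mali-over-Hampshire ratio was highest on chromosome 9, at 1.036, the mitochondrial genome, at 1.036, and chromosome X, at 1.034. It was lowest on chromosome 13, at 0.981, chromosome Y, at 0.999, and chromosome 16, at 1.005.

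GC content moved with CpG density on most sequences but not on all. It was higher in Mali on 15 of 21 sequences, most on chromosome 12 by 0.521 percentage points, chromosome 6 by 0.250 and chromosome 2 by 0.233. It was lower in Mali on chromosomes 1, 8, 11, 13, 16 and the mitochondrial genome. Of these, only chromosomes 13 and 16 were also lower in CpG density in Mali. Across autosomes the Mali-minus-Hampshire difference in GC content and the density ratio gave r = 0.886 and rho = 0.926, and r = 0.872 without chromosomes 12 and 13. Each CpG also counts toward GC content, so part of this relation is built in. The mean GC content of an autosome and its density ratio gave r = 0.671 and rho = 0.641, and r = 0.542 without chromosomes 12 and 17. Relative to the median density of each library, 18 of 21 sequences were higher in Mali. Relative to the pooled density, 8 of 21 were higher in Mali, and 10 with the pooled density of the nuclear chromosomes alone. Division by the pooled density takes the overall difference out of every sequence, so those counts show only which sequences lay above or below it.

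**Figure D3:**
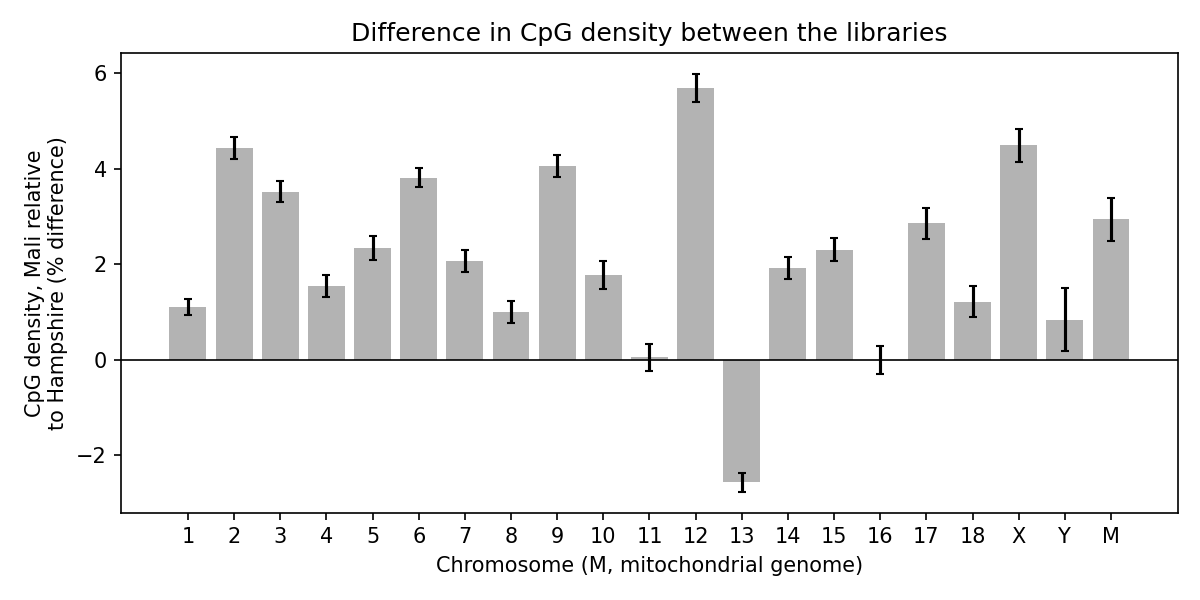
Percent difference in CpG density of the Mali library relative to the Hampshire library (vertical axis) on each chromosome (horizontal axis), with 95% counting intervals as error bars. Chromosome 12 has the tallest bar at 5.68%, and chromosome 13 is the only sequence with a clearly negative bar.

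The third comparison was of where the sequenced bases fell. The autosomes of the Hampshire library held 1.73 times as many bases as those of the Mali library (median of 18), with a range of 1.68 on chromosome 12 to 1.79 on chromosome 13 and an SD of 0.0252. The mitochondrial genome stood apart. It held 17.3 Mb in Hampshire and 17.7 Mb in Mali, so the deeper library held fewer mitochondrial bases. It took 0.415% of the Hampshire bases (interval 0.4146% to 0.4150%) and 0.736% of the Mali bases (0.7360% to 0.7367%), a share 1.78 times as large in Mali. This is 1040 and 1065 bases per base of that genome. Its reads held 2.17 CpGs per 100 bases in Hampshire and 2.23 in Mali, with 2.14 and 2.17 times as many C as G, against ratios of 1.0002 and 1.0001 in the nuclear reads. The density scores of 1.78 and 1.83 for the mitochondrial genome compare it with the whole, mostly nuclear, reference.

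The sex chromosomes also took a larger part of the Hampshire library. Relative to the median of the Hampshire-over-Mali base ratio over the autosomes, chromosome X held 1.09 times and chromosome Y 1.04 times as many bases in Hampshire as in Mali. Depth on chromosome X was 0.561 of autosome depth in Hampshire and 0.515 in Mali. Depth on chromosome Y was 0.308 of autosome depth in Hampshire and 0.298 in Mali, so both libraries held reads placed on Y. The sex of the animals is not given in the labels. Chromosome 13 held 1.03 times as many bases in Hampshire on the same scale. Chromosomes 12 and 14 held more in Mali, by ratios of 1.031 and 1.018.

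**Figure D4:**
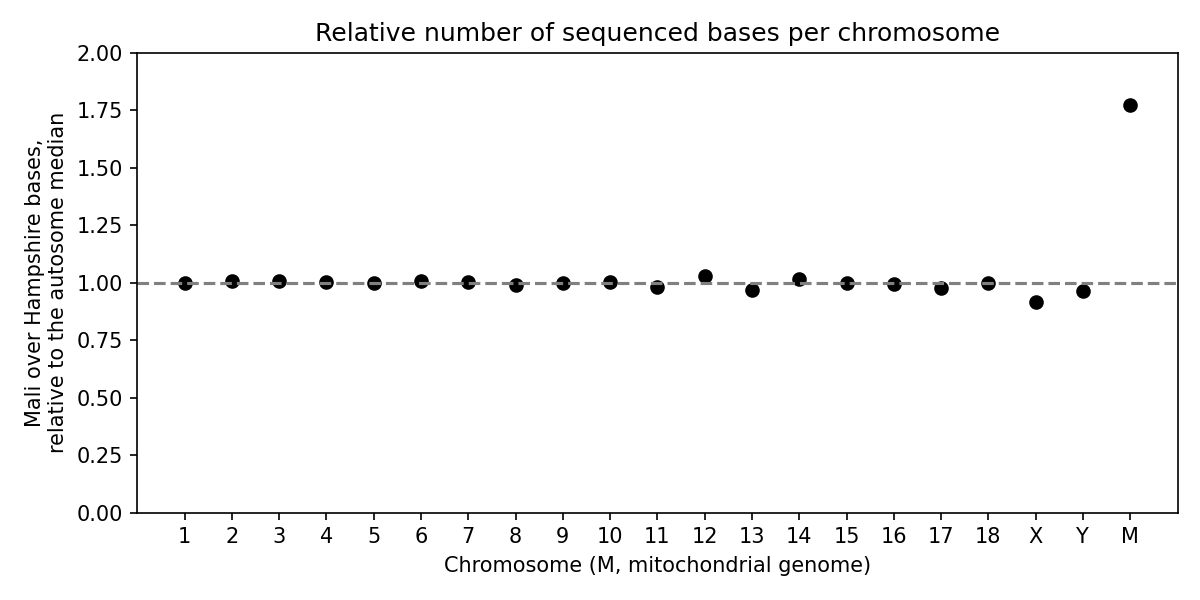
Sequenced bases in Mali over those in Hampshire, divided by the median of this ratio over the autosomes (vertical axis), for each chromosome (horizontal axis), with a dashed line at 1. The mitochondrial genome lies at 1.77, chromosome X at 0.916, and the autosomes lie between 0.967 and 1.031.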

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

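The density over the genome stayed below 1 under each summary tried: the median over sequences, 0.750 in both libraries, became 0.710 (Hampshire) and 0.729 (Mali) as a mean weighted by bases, 0.744 and 0.773 weighted by CpG count, 0.739 and 0.747 over autosomes alone, and 0.705 and 0.721 over nuclear chromosomes weighted by bases, the last chosen after seeing the data, like every setting with nuclear chromosomes or a nuclear total. The libraries' medians were thus almost equal while their pooled densities differed, because chromosome 11, where the libraries hardly differ, holds the median in both. The number of sequences denser in CpG in Mali, 19, became 18 when each library was divided by its median, 8 when divided by its pooled density, 10 when divided by its nuclear pooled density and 0 with a minimum of 1.5-fold. For observed-to-expected CpG, 19 became 19, 7, 9 and 0 in the same order. Dividing by the pooled value removes a log2 difference of 0.0393 from every sequence, so some must change sign whatever the cause; dividing by the median removes 0.000734 and turned 0 of 21 sequences. The median log2 difference in density, 0.0296, was 0.0289 after dividing by the median and -0.00970 after dividing by the pooled density. Under the latter, chromosomes 1 (-0.0234), 4 (-0.0172), 5 (-0.00593), 7 (-0.00970), 8 (-0.0250), 10 (-0.0140), 14 (-0.0118), 15 (-0.00650), 18 (-0.0219) and Y (-0.0273) also changed sign, while chromosomes 2, 3, 6, 9, 12, 17, X and the mitochondrial genome stayed higher in Mali, chromosomes 13 and 16 stayed lower, and chromosome 11, nearly equal before, went to -0.0386. Chromosomes 5 and 15, at 2.34% and 2.30% higher density in Mali, lay above the pooled nuclear difference of 2.25%. Their change of sign thus came from counting the mitochondrial genome in the pool. For sequenced bases, 1 sequence was higher in Mali as deposited, 11 after dividing by the total, 14 by the nuclear total, 6 after dividing by the median, and 0 over autosomes, over nuclear chromosomes or at 1.5-fold. Chromosome 12 changed direction by construction of the scaling, to a log2 ratio of 0.0455 (total) and 0.0376 (median). The log2 ratio of total bases, Hampshire over Mali, was 0.7936, with 0.7945 over autosomes and 0.7983 over nuclear chromosomes. Pseudocounts of 0.5 and 5 moved nothing at these counts, and leaving out the smallest sequences left the median difference at 0.0296. The gene lists and a stricter threshold were not run, because the table holds no gene values and no threshold of the authors. No paired analysis was possible because each breed has 1 library, and no library could be left out for the same reason. The precision that depth gives is not known beyond counting error, and the spread between animals was not measured.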

Other observations

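All tests in this part were chosen after the results were seen. The design names breed as the only difference between the libraries, and with 1 library each, breed, animal and library preparation stay confounded. This holds for the higher CpG density of the Mali library too. Across the 18 autosomes the log2 ratio of Mali to Hampshire bases rose by 0.00724 per percentage point of GC, with a residual SD of 0.0175. Unequal recovery of GC-rich fragments between the libraries could thus contribute to that density difference, and it was not separated from breed.

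The precipitated DNA was poorer in CpG than the genome in both libraries. Even sampling of the genome, as from a failed precipitation with no other bias, would give a density score of 1, so the pattern itself already goes against it. Depth should then also be about equal on all autosomes. It differed 1.38-fold between the highest and the lowest in Mali and 1.45-fold in Hampshire (1.26-fold and 1.25-fold without chromosome 12). Poor recovery of GC-rich fragments, with or without a working precipitation, may account for it: depth fell with GC content across autosomes, with r = -0.972 in the library with the weaker relation. A pull-down that leaves unmethylated CpG islands behind could lower the CpG content too. The pooled observed-to-expected ratio, 0.815 of the genome in the nearer library, goes with either, and these explanations cannot be told apart without an input library or values along the chromosomes.

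The mitochondrial genome took a share 1.78 times as large in Mali as in Hampshire. The mitochondrial genome lay 47.4 residual SD above the trend of the base ratio with GC content over the autosomes. Its GC content was inside the range of the autosomes, which argues against that trend as the cause. The SD is the scatter of whole autosomes and may understate that of so small a genome. The number of mitochondrial bases was almost equal in both libraries, at a Mali-over-Hampshire ratio of 1.02, although the nuclear totals differed. A ceiling from removal of duplicate reads could produce such equality on a genome this deeply covered, and more mitochondrial DNA in the Mali muscle sample may produce it by coincidence. These cannot be told apart, because the table holds 1 sum per library and the treatment of duplicates is not given.

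Chromosomes X, Y and 13 took larger shares in Hampshire, by 1.09, 1.04 and 1.03 times relative to the median base ratio of the autosomes. For X the GC trend is argued against, at -7.77 residual SD. For 13, picked as an extreme of 18 autosomes, -2.55 residual SD leaves it open. The distance of Y from the trend was not computed. Over the 17 autosomes other than 13, the trend rose by 0.00593 log2 units per percentage point of GC, with a residual SD of 0.0154. DNA of a female mixed into a Hampshire sample otherwise from a male could raise X but should lower Y to 0.911 of its Mali value. Y instead stood at 1.03 relative to the summed autosome bases, 8.52 SD of the autosome ratios above that value. Sequence shared by X and Y could hide such a fall only if it made up enough of the bases placed on Y. That part was not measured, so this stays open. A gain of the whole of chromosome 13 is argued against as the only cause by base composition, which it should leave unchanged. The C-to-G ratio of its reads differed between libraries by 5.48 SD of the other 17 autosomes. A gain together with some added sequence of skewed composition stays open, because the ratio does not show how much of the surplus is skewed. The surplus over the autosome ratio, 13.2 Mb of sequence (11.1 to 15.6 Mb at the quartiles of that ratio), had 1.09 to 1.27 CpGs per 100 bases and 1.19 to 1.27 times as many C as G if both libraries had the same baseline composition, and 1.57 CpGs and a C-to-G ratio of 1.204 if each count was scaled by its own autosome median; a local pile-up of reads is a candidate explanation that was not tested.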
